A study of Populus tremula x Populus tremuloides with 12 samples.

How the data were processed

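RNA came from leaves at plastochron positions 7 to 10 of hybrid poplar, and per the labels' protocols mRNA was enriched with magnetic beads, fragmented and made into libraries with a NEBNext Ultra kit. The 12 libraries were pooled for sequencing. The labels name 6 WT and 6 OE plants, of which 3 of each were moved into sunlight. Whether the OE plants came from 1 transgenic line or several is not given in the sources used here.

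The submitters' processing notes name TopHat2 2.1.1, Cufflinks and HTSeq 0.6.1 without saying what each was used for. The genome build and annotation are not given in the sources used here. The deposited files hold raw read counts per gene, not normalized, as their values show: all 33980 entries of each library are whole and 0 or above, and library totals differ. Other than the counts of 33975 genes, each file ends in 5 summary entries, which were kept out of library sizes and tests. Of all reads, between 6.85% and 32.2% lay outside annotated genes, between 3.99% and 6.59% were ambiguous between genes, and between 3.73% and 5.8% aligned to more than 1 place. Reads that aligned to more than 1 place were set apart from the gene counts, so near-identical genes can lose reads. How the counting treated strand is not given in the sources used here, so overlapping genes can gain or lose reads.

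The quasi-likelihood test of edgeR had been planned as the main test and DESeq2 as an alternative, and they were not run. The files are tab-separated under a name for comma-separated tables, and an automatic reading of their units could not read the count column. The unit was therefore declared as "other" although the values are counts, which skips the automatic check of the values and rules out both tools. Instead, counts were analysed with limma 3.58.1 in R 4.3.3, chosen after the files were opened. The trimmed mean of M values (TMM) and median-of-ratios scalings and the filter were written out in R. Genes were kept with at least 10 counts at the median library size (0.69 CPM) in at least 3 libraries and at least 15 counts in all. This left 22959 genes, and 4288 of the listed genes had no count in any library. TMM trimmed 30% of the log ratios and 5% of the levels from each end. The voom weights, 1 mean per group over all 12 libraries, robust empirical Bayes and Benjamini-Hochberg adjustment over genes followed, with adjusted p under 0.05 as the threshold. Fold changes are limma estimates. CPM values use the TMM-scaled library sizes. For a gene with 1 to 3 counts in a group, the ratio of summed counts is given with its exact 95% counting interval, which covers counting error only.

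Simulated data with the libraries' sizes, and 100 genes changed 2-fold and 100 changed 4-fold, were used to test the fit. Their spread was that within groups, averaged over genes of similar level. No single gene or library was given a larger spread of its own. For OE against WT in the greenhouse 50% and 94% were recovered, in sunlight 61% and 95%, for sunlight in WT 51% and 97%, for sunlight in OE 57% and 98%, and for the difference between effects 26% and 79%. Between 4 and 10 unchanged genes were called per simulation. The scaling was tested in a separate simulation, in which a small share of genes was raised 8-fold in OE greenhouse alone. There TMM factors came within 0.025 (log2) of the simulated ones and median-of-ratios factors within 0.03.

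Replicates were compared before averaging, and no pair agreed within sampling noise: chi-square per degree of freedom was between 12.0 and 70.3. Gene counts per library were 8480528, 9234588 and 17618035 in WT greenhouse, 15651021, 10672128 and 20052212 in OE greenhouse, 14361506, 14614245 and 23184358 in WT sunlight, and 5870132, 9484234 and 27711999 in OE sunlight. A count of 0 in a library allows up to 3 counts, which is 0.479 CPM in the shallowest and 0.104 CPM in the deepest.

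The groups, comparisons, named-gene rule and most alternatives were fixed before the data were examined. Genes are named by that rule: for each comparison of 2 groups, the 2 called genes of each direction with the largest absolute log2 fold change, a mean of at least 1 CPM in the higher group and no overlap between libraries. Chance gives no overlap for 10% of genes with 3 against 3. Potra198651g30163 was chosen after its values were seen. Lists of genes by function had been fixed on gene descriptions. They were not applied, because no descriptions of these IDs were used here, and no set test was run. Alternatives were other scalings, no filter, a non-robust fit, a 2-fold limit, the compared libraries alone, a replicate block and each library left out in turn. Those added after seeing the data were limma-trend, library quality weights, library totals alone, both libraries that stand apart left out, libraries outside the compared groups left out in turn, and, for the overlaps, no filter, the non-robust fit, the compared libraries alone and single libraries left out.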

Results

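Transcript levels were measured by RNA sequencing in leaves of hybrid poplar, a cross of Populus tremula and Populus tremuloides. Wild-type plants (WT) were set beside plants carrying a vector for overexpression of MYB165 (OE), a MYB transcription factor described in poplar as a repressor of phenylpropanoid and flavonoid synthesis. Leaves at plastochron positions 7 to 10 were taken after 2 months in the greenhouse, with or without 1 further week outdoors in sunlight. The sunlight plants thus had 1 more week of growth and another site. Sunlight itself cannot be told apart from age or other outdoor conditions, and "sunlight" below names the whole difference. Each of the 4 groups held 3 libraries from separate plants, 12 in all. The libraries carried between 5870132 gene counts (OE sunlight 2) and 27711999 (OE sunlight 6), and 22959 of the 33975 listed genes had enough counts to be tested. The files give gene IDs that they do not pair with names, so genes are given by ID and MYB165 itself was not analysed here.

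Levels are given as CPM, the counts scaled to a common library size. The first principal component of log2 CPM held 36.4% of the variance and the second 20.2%. On the first, all 6 OE libraries scored above all 6 WT libraries. On the second, the sunlight libraries of each genotype scored below its greenhouse libraries. OE greenhouse 3 stood apart at 116 on the first component, against 44.7 and 47.4 for the other 2 libraries of its group, and its correlation with each of them was 0.939, the lowest among replicates.

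**Figure D1:**
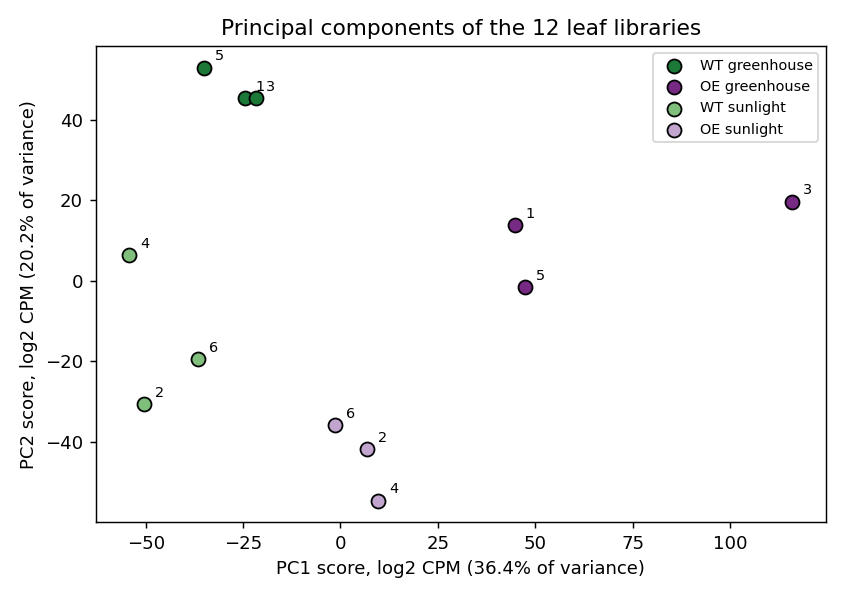
Scores of the 12 libraries on the first and second principal components of log2 CPM, coloured by group and marked with the replicate number. OE libraries lie to the right of WT libraries, and OE greenhouse 3 lies at 116 on the first component.

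The first comparison asked how leaves of OE plants differed from WT in the greenhouse. By the fitted value, the largest rise among genes meeting the naming rule was that of Potra000033g00168, at 11.7 ± 1.26 CPM in WT and 1230 ± 196 CPM in OE (SD, n = 3 each). This was a log2 fold change of 6.70 ± 0.38 (SE), or 104-fold, with limma adjusted p = 5.64e-06. Potra008842g26239 rose from 3 counts in all of WT to 157 in OE, a count ratio of 33.8 (95% counting interval 11.4 to 166). The limma adjusted p of its fitted change was 0.00304. Potra006413g25676 fell from 13.9 ± 2.11 CPM to a single count over the 3 OE libraries, where WT exceeded OE by a count ratio of 689 (95% counting interval 123 to 27300). The limma adjusted p of its fitted change was 0.00518. Potra002126g16486 fell from 74.5 ± 42.7 to 0.301 ± 0.288 CPM (SD, n = 3 each), with a log2 fold change of -7.99 ± 1.41 (SE) and limma adjusted p = 0.0109.

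In the greenhouse 1094 genes passed adjusted p under 0.05, of which 523 were higher and 571 lower in OE. Large changes were mostly decreases: 100 genes were at least 8-fold lower by the fitted value and 27 at least 8-fold higher. WT greenhouse 5 had 32.2% of its reads outside genes, against 7.05% and 16.4% in the other WT greenhouse libraries, and the count was 269 without it, 466 without WT greenhouse 3, 686 without WT greenhouse 1, 704 without OE sunlight 6 (which shares the estimate of the spread) and 317 in a fit of the 6 greenhouse libraries alone. Scaling by library totals took the median log2 fold change of all genes from 0.011 to 0.23 and turned the split to 1245 higher and 334 lower, and the call of Potra002126g16486 was lost without OE greenhouse 3, as were those of Potra002126g16486 and Potra006413g25676 without both OE greenhouse 3 and WT greenhouse 5. The log2 fold change of Potra002126g16486 was -8.69 without OE greenhouse 1, -8.61 without WT greenhouse 3 and -7.28 without OE greenhouse 5, and the fitted one of Potra008842g26239, 4.74 with all libraries, was 3.82 without WT greenhouse 5 and 5.33 without WT greenhouse 3.

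The second comparison asked the same of plants moved into sunlight. Potra000033g00168 again had the largest fitted rise among genes meeting the naming rule, at 17.2 ± 9.33 CPM in WT and 981 ± 76.4 CPM in OE (SD, n = 3 each), a log2 fold change of 6.02 ± 0.35 (SE) or 64.9-fold with limma adjusted p = 8.18e-06. Potra002559g19287 rose from 1 count in all of WT to 104 in OE, a count ratio of 127 (95% counting interval 22.3 to 5060). The limma adjusted p of its fitted change was 0.0376. Potra002126g16486 fell from 163 ± 95.8 to 1.72 ± 0.654 CPM (SD, n = 3 each), an 83.9-fold decrease with limma adjusted p = 0.00247. Potra010120g26493 fell from 16.6 ± 8.29 to 0.17 ± 0.0668 CPM (SD, n = 3 each), a 67.5-fold decrease with limma adjusted p = 0.00869. Its OE level rested on 9 counts in all.

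In sunlight 286 genes passed the threshold, 84 higher and 202 lower in OE. The fitted decreases had a median log2 fold change of -2.50 and the increases one of 1.47, and 83 genes were at least 8-fold lower against 5 at least 8-fold higher. The count was 151, 137 and 123 without OE sunlight 2, 4 and 6, 187 without WT sunlight 4, and 494 without OE greenhouse 3, which shares the estimate of the spread. The split into higher and lower was 222 and 272 without OE greenhouse 3, 317 and 400 with library quality weights, and 25 and 119 with a replicate block. The calls of Potra002559g19287 and Potra010120g26493 were each lost when any 1 OE sunlight library was left out, that of Potra002559g19287 also when any 1 WT sunlight library was, and that of Potra002126g16486 without OE sunlight 6. The single WT count of Potra002559g19287 lay in WT sunlight 2, without which its fitted log2 fold change was 6.41 in place of 5.76.

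Genes called for OE were shared between conditions beyond independent lists. Of the tested genes, 160 were lower in OE both in the greenhouse and in sunlight, where independent lists would share 5.0, and 59 were higher in both, where independent lists would share 1.9. No gene was called in opposite directions. The 2 contrasts share no library, but they share the estimate of each gene's spread, so their calls are not independent. With only the compared libraries in each fit, 109 genes were lower in both and 31 higher in both. Across the 1161 genes called in either condition, which are not independent replicates, the log2 fold changes correlated at r = 0.89 and 94.1% had the same sign, and over all 22959 tested genes r was 0.66. The genes summed next were chosen by their calls in these same libraries, so the sums describe the sets and do not test them. The 160 lowered genes summed to 16400 ± 5510 CPM in WT and 1900 ± 181 CPM in OE in the greenhouse, and to 19100 ± 5560 and 2730 ± 362 CPM in sunlight (SD, n = 3 each). Their median level was 25.3 CPM in WT greenhouse and 2.43 CPM in OE greenhouse, and 58 of them averaged under 1 CPM in OE greenhouse. The 59 raised genes summed to 2050 ± 164 CPM in WT greenhouse, 7250 ± 254 in OE greenhouse, 2010 ± 31.3 in WT sunlight and 6080 ± 357 in OE sunlight (SD, n = 3 each). Without OE sunlight 2, 4 and 6 the count lower in both was 99, 94 and 72, and the count higher in both was 30, 27 and 33. The count higher in both was also 144 without OE greenhouse 3, 36 without WT greenhouse 5, 35, 35 and 38 without WT sunlight 2, 4 and 6, and 31 with only the compared libraries in each fit.

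**Figure D2:**
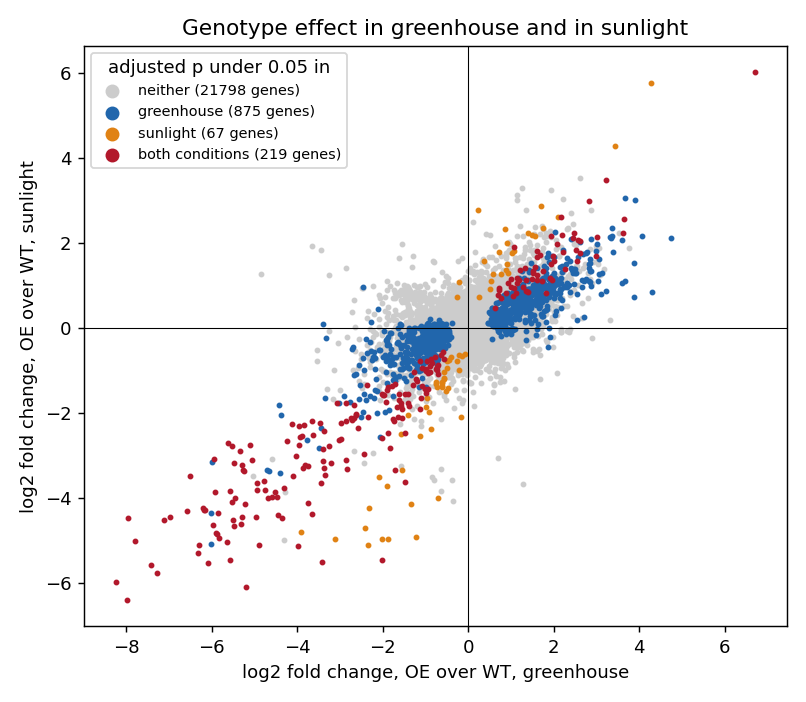
Fitted log2 fold change of OE over WT for each of the 22959 tested genes, in the greenhouse (horizontal) and in sunlight (vertical), coloured by the conditions in which adjusted p was under 0.05. The 219 genes called in both conditions lie in the lower left and upper right quadrants, 160 lower and 59 higher in OE.

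**Figure D3:**
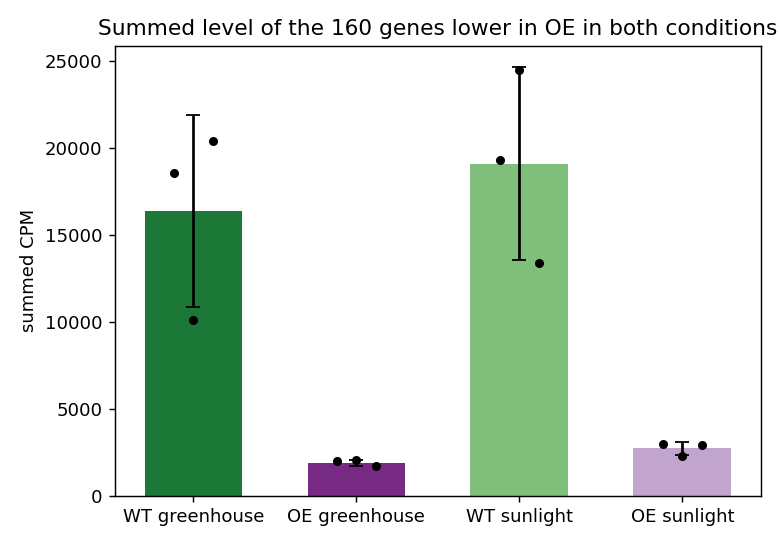
Summed CPM of the 160 genes lower in OE in both conditions. The genes were chosen by their calls in these same libraries, so lower OE bars follow from the choice. Bars give the mean of 3 libraries, error bars the SD and points the single libraries, and the OE bars stand at 1900 and 2730 CPM against 16400 and 19100 CPM in WT.

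The third comparison asked how WT leaves differed after 1 further week in sunlight from those of the greenhouse. Potra001768g14372 rose from 0.468 ± 0.299 CPM in the greenhouse to 22.3 ± 12.9 CPM in sunlight (SD, n = 3 each), 43.6-fold with limma adjusted p = 0.0146. Potra166498g27221 rose from 1.16 ± 0.594 to 55.4 ± 41.8 CPM (SD, n = 3 each), 34.9-fold with limma adjusted p = 0.0484. Potra001065g09170 fell from 581 ± 87.6 to 7.35 ± 2.87 CPM (SD, n = 3 each), an 81.4-fold decrease with limma adjusted p = 0.0031. Potra187831g28542 fell 66.7-fold, from 53.7 ± 10.1 to 0.806 ± 0.357 CPM (SD, n = 3 each), with limma adjusted p = 0.0054.

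In WT 322 genes passed the threshold for sunlight, 146 higher and 176 lower. The count was 148, 34 and 39 without WT greenhouse 1, 3 and 5, and 59, 194 and 151 without WT sunlight 2, 4 and 6. Of the OE libraries, which share the estimate of the spread, leaving out OE greenhouse 3 gave 1026, OE sunlight 2 gave 198 and OE sunlight 6 gave 130. Scaling by library totals gave 760 higher and 110 lower, with the median log2 fold change of all genes going from 0.0051 to 0.23, and the call of Potra001768g14372 was lost without WT greenhouse 3 or 5 and that of Potra166498g27221 without any 1 of the WT greenhouse libraries or WT sunlight 4 or 6. Both calls were also lost in a fit of the 6 WT libraries alone and without both libraries that stand apart, and that of Potra166498g27221 with no filter, and its log2 fold change of 5.13 was 5.87 and 4.54 without WT sunlight 2 and 6.

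The fourth comparison asked the same of OE leaves. Potra194265g28942 rose from 2 counts in all of OE greenhouse to 61 in OE sunlight, a count ratio of 33.0 (95% counting interval 8.75 to 279). The limma adjusted p of its fitted change was 0.0476. Potra188671g28625 rose from 0.127 ± 0.11 to 2.34 ± 0.977 CPM (SD, n = 3 each), 19.2-fold with limma adjusted p = 0.0255. Its greenhouse level in OE rested on 7 counts in all. The WT levels of Potra188671g28625 were far higher, at 35.5 ± 12.3 CPM in the greenhouse and 58.8 ± 8.65 CPM in sunlight. Potra003940g23658 fell from 26.1 ± 21.2 to 1.1 ± 0.584 CPM (SD, n = 3 each), an 18.3-fold decrease with limma adjusted p = 0.0242. Potra169505g34200 fell from 8.41 ± 3.64 to 0.547 ± 0.29 CPM (SD, n = 3 each), a 14.2-fold decrease with limma adjusted p = 0.00529.

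In OE 1121 genes passed the threshold for sunlight, 667 higher and 454 lower, with medians of 0.86 and -1.03 on the log2 scale. The split was 240 higher and 244 lower with a 2-fold limit, 1241 and 1245 with library quality weights, and 83 and 31 without OE sunlight 6. The count was 608, 186 and 114 without OE sunlight 2, 4 and 6, 686 without WT greenhouse 3, and 48 in a fit of the 6 OE libraries alone, in which none of the 4 genes named here was called (Potra194265g28942 was not tested there). The calls of Potra194265g28942 were lost when any 1 OE library was left out, those of Potra188671g28625 in that way for 5 of the 6, those of Potra003940g23658 without OE sunlight 4 or 6, and those of Potra169505g34200 without OE sunlight 6. Without OE greenhouse 3 the log2 fold change of Potra188671g28625 was 3.62 in place of 4.26 that of Potra003940g23658 was -3.60 in place of -4.20, and the fitted one of Potra194265g28942, whose 2 greenhouse counts both lay in that library, was 5.55 in place of 4.56. The call of Potra194265g28942 was also lost without both libraries that stand apart.

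Genes called for sunlight were also shared between genotypes, in numbers that changed strongly when single libraries were left out. There were 86 genes higher in sunlight in both genotypes, against 4.2 for independent lists, and 85 lower in both, against 3.5. No gene was called in opposite directions. Here too the 2 contrasts share no library but share the estimate of each gene's spread, so their calls are not independent. Across the 1272 genes called in either genotype r was 0.77 over genes and 96.1% had the same sign, and over all tested genes r was 0.54. As above, the direction of the sums follows from the choice of genes. The 86 raised genes summed to 2600 ± 154 CPM in WT greenhouse and 7180 ± 245 in WT sunlight, and to 2250 ± 224 and 5550 ± 79.4 CPM in the OE groups (SD, n = 3 each). The 85 lowered genes summed to 7560 ± 155 CPM in WT greenhouse and 3220 ± 154 in WT sunlight, and to 8230 ± 125 and 3400 ± 158 CPM in OE (SD, n = 3 each). The counts higher and lower in both were 175 and 159 without OE greenhouse 3, 37 and 24 without OE sunlight 4, 20 and 13 without OE sunlight 6, and 7 and 8 with only the compared libraries in each fit, and the count lower in both was 35 without OE sunlight 2. They were 32 and 41, 7 and 13, and 10 and 21 without WT greenhouse 1, 3 and 5, and 18 and 15, and 45 and 51 without WT sunlight 2 and 6. Scaling by library totals gave 244 higher and 58 lower in both.

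The last comparison tested whether the OE effect differed between conditions. With limma no gene passed adjusted p under 0.05, the smallest adjusted p being 0.557. At an unadjusted p under 0.05 there were 1377 genes, where chance gives 1148, and a limma-trend fit also called 0. That number was 870 without WT greenhouse 5, 810 without both libraries that stand apart and 2068 with library totals as the scaling, and so lay on either side of chance. Potra001065g09170 illustrates the size of the differences that stayed under the threshold: its OE over WT log2 fold change was -1.56 in the greenhouse and 1.98 in sunlight, a difference of 3.54 ± 0.90 (SE) with limma adjusted p = 0.818. Simulated counts with a 4-fold difference between the effects were recovered in 79% of cases and those with a 2-fold difference in 26%, so differences of about 2-fold were mostly not detectable here. The simulated spread was averaged over genes of similar level, so these shares may be too high for genes with a larger spread. The absence of calls does not rule out 4-fold or larger differences, such as that fitted for Potra001065g09170. Genes called in 1 condition or genotype are therefore not shown to respond differently in the other.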

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

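The tests of the abundant RNA and of wrong labels were chosen only after the result was seen, as was the count of splits for the difference between effects. In sunlight, 2 OE libraries had a larger share of reads outside genes than any WT library there. The share was 13.06% in OE sunlight 2 (exact 95% binomial interval 13.04% to 13.09%) and 8.474% in OE sunlight 4 (8.458% to 8.49%), against at most 7.744% in WT sunlight. The intervals cover counting error only. No group was tested for single extreme libraries, since each holds 3.

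The highest shares were in WT greenhouse 5, at 32.2%, and WT greenhouse 3, at 16.4%. Genomic DNA would place reads in silent genes: the 4519 genes without a count in the 9 libraries of the other groups had 113 counts in WT greenhouse 5 and 163 in WT greenhouse 1 and 3, a ratio of 0.545 relative to all reads (exact 95% interval 0.425 to 0.697), which argues against it. Of these genes 4288 had no count in any library, so the ratio rests on the remaining ones. The interval covers counting error only, and WT greenhouse 3, with a high share itself, is among the libraries compared. For a single RNA carried through mRNA selection no value decides: Potra198651g30163 took 4.95% of gene counts in WT greenhouse 5 and 1.47% in WT greenhouse 3. Over the 12 libraries its share correlated with the share outside genes at Pearson r = 0.993 and r was 0.977 without those 2 libraries, but the gene was picked for being high where this share was high, so the correlation does not test the explanation, which stays open. No biological explanation was tested, and without WT greenhouse 5 the greenhouse count of OE genes was 269 in place of 1094.

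OE greenhouse 3 deviated from the other 2 libraries of its group by 0.778 (root mean square, log2), the largest of the 12. With all libraries thinned to the smallest total it was still the largest, at 0.684 against at most 0.521 elsewhere, which argues against depth. A wrong genotype label is argued against by its position of 1.06 on the 875 genes called between the genotypes in the greenhouse without it (WT at 0, the other OE greenhouse libraries at 1). A wrong condition label is argued against by a position of 0.15 on the 1026 genes called for sunlight in WT in a fit without this library (WT greenhouse at 0, WT sunlight at 1). A difference between plants or transgenic lines stays open and was not tested.

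Other splits of the same libraries were fitted in the same way. With 3 libraries against 3 there are 10 splits, so no share under 0.05 is possible. In each of the 4 comparisons 1 of the 10 splits, the real one, gave as many genes. The real counts were 1094 for OE in the greenhouse (highest other 0), 286 for OE in sunlight (highest other 1), 322 for sunlight in WT (highest other 0) and 1121 for sunlight in OE (highest other 0). Every other split mixes libraries of both real groups, so a real difference would enter its within-group spread and lower its calls. The other counts therefore do not show what groups without any difference would give. For the difference between effects the real count was 0, which any split reaches, so that all 100 drawn splits gave as many (the highest other 15) decides nothing.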

How the results depend on the processing

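Settings added after seeing the data are named as such in the methods. DESeq2 and the list tests were not run. Of 231 alternative values for the 16 named results, with the 2-fold limit left out because it moves none of them, 188 stayed past the threshold and 43 did not. Counts stayed within 1.5 times under median-of-ratios scaling, no filter, the non-robust fit and limma-trend. Where they did not, the cause was not tested, except that a fold limit can by construction only lower a count. Leaving out 1 library moved counts both ways. It leaves 2 libraries in that group, eases the filter to 2 libraries and gives less information on the spread. A lower count then does not show that the calls rested on the library left out. In this order (OE in greenhouse, OE in sunlight, sunlight in WT, sunlight in OE), the main counts were 1094, 286, 322 and 1121, and library quality weights gave 1849, 717, 2205 and 2486. A 2-fold limit gave 726, 198 and 484 for the first and the last 2. The 6 compared libraries alone gave 317 for the first and 48 for the last. Without both libraries that stand apart the first was 324 and the last 714. Library totals gave 870 for sunlight in WT, and changed the share of higher calls from 47.8% to 78.8% for OE in the greenhouse and from 45.3% to 87.4% for sunlight in WT. Leaving out 1 of the 12 libraries gave 269 to 1202, 123 to 494, 34 to 1026 and 114 to 1236, and 0 to 1 for the difference between effects, the 1 being without WT sunlight 2.

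For the overlaps, genes lower in OE in both conditions numbered 160, and 260 with quality weights. Those higher numbered 59, 215 with quality weights and 31 with the compared libraries alone. Leaving out 1 library gave 72 to 184 and 27 to 144. Genes higher in sunlight in both genotypes numbered 86, with 457 under quality weights, 244 under library totals (with 58 lower), 43 with a 2-fold limit and 7 with the compared libraries alone. Those lower numbered 85, with 465, 44 and 8 under quality weights, the limit and the compared libraries alone. Leaving out 1 library gave 7 to 175 and 13 to 159.

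The label numbers do not pair the libraries: same-numbered libraries' deviations correlated at -0.159, 0.056 and -0.204 in the greenhouse and -0.089, -0.438 and -0.113 in sunlight, and 1 of the 6 WT libraries correlated best with its own number. A replicate block gave 407 genes for OE in the greenhouse, 144 in sunlight, 97 lower and 19 higher in both, and 0 for the difference. Depth limits the low genes most in OE sunlight 2, with 5870132 counts.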

Other observations

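The tests of reads from other libraries and of sunlight-raised genes were chosen only after the result was seen. The 160 genes lower in OE in both conditions stood higher in OE sunlight than in OE greenhouse. Their mean log2 CPM was 2.57, 2.30 and 2.64 in OE sunlight 2, 4 and 6 and 1.96, 1.99 and 1.87 in OE greenhouse 1, 3 and 5. The difference was 0.56 (exact permutation test, two-sided p = 0.1, the smallest 3 against 3 allows), and between the WT groups it was 0.29. The genes were chosen by their calls in these same libraries. The permutation test covers the OE groups alone and does not ask whether OE rose more than WT. Reads leaking from other libraries of the pool, in equal number into each library, would weigh most in the shallowest library. OE sunlight 6 was 4.72 times deeper than OE sunlight 2. Yet the summed CPM of these genes in OE sunlight 2 was only 1.02 times that in OE sunlight 6, which argues against such a leak. A leak in proportion to a library's own reads would not show in this ratio, so that source stays open. A real effect of sunlight on these genes stays open as well.

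Potra000033g00168 had the largest fitted rise among genes meeting the naming rule in both conditions and lay between 912 and 1440 CPM in all 6 OE libraries, against 8.4 to 27 CPM in the 6 WT libraries. Whether it is the introduced gene was not tested, since the IDs are not paired with names here.

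As a hypothesis, genes with neighbouring numbers might share the OE response. Among 16003 adjacent tested pairs on the same sequence, 4 pairs were both lower in OE in both conditions, where 10000 permutations gave 0.78 on average and at most 5 (permutation p = 0.008). Of the 59 raised genes no pair was adjacent (permutation p = 1). Permutations of this smaller set gave only 0.1 pairs on average, so the lack of pairs does not set the raised genes apart from the lowered ones. The 4 pairs may be copies of a gene, which was not tested.

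A second hypothesis was that OE lowers genes that sunlight raises in WT. Of those raised by sunlight in WT, 22 were lower in OE in sunlight (1.3 for independent lists) and 0 higher, but both contrasts contain the WT sunlight libraries, whose chance values push the overlap that way. Of the same genes, 12 were lower in OE in the greenhouse (3.6 for independent lists) and 11 were higher (3.3). There the shared WT greenhouse libraries push the other way, toward genes higher in both, so the 12 run against that push and the 11 with it, and the 2 counts cannot be weighed against each other. Of the genes lowered by sunlight in WT, 24 were also lower in OE in the greenhouse (4.4 for independent lists), more than the 12, though the shared libraries push toward this overlap as well. The covariance of the fold changes over genes was -0.0479 in sunlight and 0.0581 in the greenhouse, against means of -0.0408 and 0.0494 in 30 simulations without effects, where the shared libraries alone give it. The correlations were -0.19 and 0.16, against simulated means of -0.46 and 0.54. In these simulations at most 0 genes were called higher in sunlight in WT and lower in OE. No simulated gene had an effect to be called, so this does not weigh the 22 or the 12. The hypothesis stays undecided.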
